A study of Mus musculus with 2 samples.

How the data were processed

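The data were an anti-FLAG chromatin immunoprecipitation followed by sequencing (ChIP-seq) of mouse palatal shelves, the paired outgrowths of the maxilla that fuse to form the palate. Per the labels, the embryos were homozygous for a 3xFLAG tag added to the endogenous Foxf2 gene by genome editing, and shelves of 50 pairs were collected at E13.5 (embryonic day). There was 1 ChIP library and 1 input library, and no replicate of either. Per the labels' protocols, nuclei were sonicated and libraries were made with a ThruPLEX kit.

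Reads were aligned to the mouse build mm9, and the tools named were Bowtie 1.0.0, SAMtools 0.1.19 and HOMER, per the submitters' processing notes. HOMER's version is not given in the sources used here. Per the file headers, peaks were called on the 1 ChIP library against the 1 input library with HOMER findPeaks in its histone style, in which neighbouring 500 bp peaks are stitched into wider regions. Per the file headers, the fragment length was 112 bp, at most 1 tag was kept per position, and the minimum distance between peaks was 1000 bp. Per the file headers, the Poisson tag threshold was 17, and a peak needed a 10-fold excess over input and a 10-fold excess over the surrounding 10000 bp, each with a Poisson p-value of at most 0.0001. Peaks were not called per replicate, so no overlap between replicates could be measured.

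The deposited signal was the ChIP tag number of each peak scaled to 10000000 tags, per the file headers. Multiplied back by the total of 26849463 tags, each value lay within 0.134 of a whole number (tolerance 0.15), and the whole numbers summed to 397999, the header's total of tags in peaks. The deposited coverage columns also held the ChIP tags scaled to the input depth and the unscaled input tags, with 0.5 written where a peak had no input tag. The deposited fold was the quotient of these columns, and it put the input depth at about 19230000 tags. The deposited score was the peak caller's own score, and the p-value column was the authors' Poisson p-value against input. Score, fold and p-value were used to describe, rank and filter peaks within this list, and to compare peaks with and without a motif. The score was also thinned at random for the X chromosome in the closing section. The deposited clonal fold column entered no test. The input library's own file was not used here.

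Chromosome names and peak ends were compared with the NCBIM37 reference, which is the assembly of mm9, and coordinates are given 1-based on that build with GENCODE vM1 genes. Each peak was represented by its centre. Centres were compared with 1000 sets of positions redrawn uniformly on the same chromosome outside assembly gaps, with a 2-sided permutation p. Mappability was not modelled in the redrawn positions. A peak was assigned to the gene with the nearest protein-coding transcription start site (TSS) if that lay within 100 kb. Annotated alternative starts counted, so distances are to the nearest annotated TSS of the gene.

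Motifs were searched on both strands in the 200 bp around each centre and in a window of the same width 2000 bp upstream, and the paired counts were compared with an exact McNemar test. The 22 motifs, the forkhead sequence RTAAAYA among them, were adjusted together by Benjamini-Hochberg (R stands for A or G, Y for C or T, W for A or T, S for C or G, N for any base). Median scores were compared by a 2-sided permutation test with 100000 resamples, and shares near and far from a TSS by a 2-sided Fisher exact test. Shares carry Wilson 95% intervals. A peak's fold carries an exact 95% interval conditional on its ChIP and input tags. Intervals cover counting error only, since PCR copies of a fragment are not independent molecules.

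The 16 gene lists held palate regulators, forkhead genes, the hedgehog, FGF, TGF-beta/BMP and Wnt pathways, extracellular matrix genes, osteogenic genes, markers of epithelium, endothelium, neural cells, muscle, and blood and macrophages, liver genes, ribosomal protein genes and cell cycle genes. Of 466 entries, 463 matched a protein-coding gene name, 8 of them through an older symbol such as Foxf1a for Foxf1, Mtap2 for Map2 and Sfpi1 for Spi1. For each list, the number of genes with an assigned peak was compared with 10000 random lists of the same size, matched on decile of the length of sequence assigned to a gene (2-sided permutation p, Benjamini-Hochberg over the 16 lists). Genes were named by a rule: the nearest genes of the 10 highest-scoring peaks, the 10 genes with the most assigned peaks (ties broken by summed score), the 4 highest-scoring genes of each list (up to 3 in lists of other cell types), and always Foxf2, Foxf1, Foxe1, Fgf18, Shh, Ptch1, Osr2, Pax9, Msx1, Tgfb2 and Bmp4. Where a count of 5 or fewer genes fell outside the rule, those genes were named after their values were seen. Single-gene results of some list members are not reported here. Groups, tests, lists, motifs, the naming rule and most alternatives were chosen before the data were examined.

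With 1 library per group, every p-value describes this peak list and not the spread between animals, and peaks and genes are not replicates. The statistical steps were tested on simulated data of the same size. Random lists were called in 4.5% of 200 draws, and all of 50 lists of 40 genes with 20 planted peaks were called (100.0%). These lists were random genes and their peaks were placed uniformly. They therefore test the computation, not whether matching on assigned length suits peaks that gather at promoters. A 20% share of positions planted at TSSs was recovered as 20.04%, a motif planted in 10% of windows as 10.05%, and a score shift of 5 as 5. The ratio of centre to flank without a planted motif was 1.02. Alternatives changed the peaks kept, motif, window, background, promoter width, TSS set, assignment rule and statistic, and the closing section gives their effect. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.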

Results

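Binding of Foxf2, a forkhead transcription factor of the palatal mesenchyme, was mapped in mouse palatal shelves at embryonic day E13.5 through a FLAG tag on the endogenous protein. The comparison was between 1 anti-FLAG ChIP library of 26849463 tags and 1 input library, whose depth followed from the peak values as about 19230000 tags. There were no replicates, so differences between peaks have no replicate check. The question was which genes lie near Foxf2 binding in the developing palate.

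The peak list held 9165 Foxf2-FLAG regions on 21 chromosomes, covering 5.45 Mb. Peaks held 1.48% of the ChIP tags. Of the regions, 5997 (65.4%) were 500 bp wide and 3168 were wider, up to 2598 bp. The median peak had 30 ChIP tags (range 14 to 693), 2 input tags and a 12.9-fold excess over input (range 10.03 to 173). At most 20 ChIP tags were counted in 2658 peaks (29.0%), 587 (6.40%) had no input tag, and 6093 (66.5%) were under 15-fold. Relative to the genome mean of each library, the median peak had 4.17 times the ChIP tags and 0.219 times the input tags. Peak density was 3.75 per Mb over the autosomes, with chromosome 11 at 4.34 (95% interval 3.97 to 4.73) and chromosome 14 at 2.91 (2.62 to 3.23). The X chromosome had 195 peaks, 1.20 per Mb (1.04 to 1.38), and the Y chromosome had 1.

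The highest-scoring peak lay in an intron of Wdr37, at chromosome 13:8828925-8829553 (mm9), with a score of 271. It held 279 ChIP tags against 6 input tags, a 33.3-fold excess (95% interval 15.1 to 91.5). Its forkhead sites included GTAAACA at 8829164-8829170 on the plus strand, in the context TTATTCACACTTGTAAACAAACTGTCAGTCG. The next peak by score (209) was assigned to Twist1, which encodes a basic helix-loop-helix factor of cranial mesenchyme, although other peaks lay nearer to Twist1. It lay at chromosome 12:34736623-34737752, 94.7 kb downstream of the Twist1 TSS, and its centre was in coding exon 15 of an Hdac9 transcript (34735090-34737205). It had 693 ChIP tags against 23 input tags (21.6-fold, 14.3 to 34.3), the most ChIP tags of any peak, and 7 forkhead sites. The nearest of these to the centre was ATAAACA at 34737214-34737220, in the context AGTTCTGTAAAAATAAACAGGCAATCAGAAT.

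The other 8 of the 10 highest-scoring peaks lay nearest to 4731417B20Rik, Dnajb9, Ube2v2, Gm8325, Col4a3, Btbd8, Frmd4a and Satb1, with scores of 171 to 189. The Col4a3 and Frmd4a peaks were intronic, the Btbd8 peak lay 0.1 kb from the TSS, and the others were intergenic. The Dnajb9 peak (chromosome 12:44073708-44074340) was 1237 kb from the gene and was the 1 of the 10 with no RTAAAYA site.

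**Figure D1:**
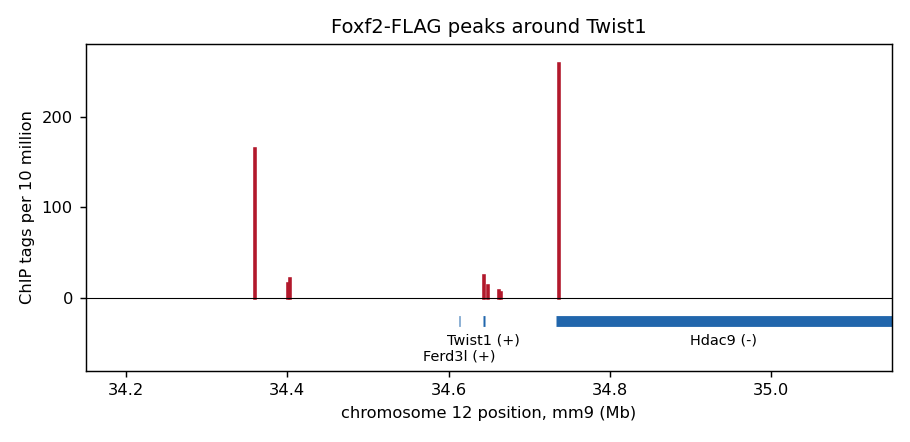
Foxf2-FLAG peaks around Twist1 on chromosome 12 (mm9). The x axis gives position in Mb and the y axis the deposited ChIP signal in tags per 10000000. Each bar is a peak, blue boxes are genes with their strand, and the tallest bar (258.1) lies at the 3′ end of Hdac9.

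Foxf2-FLAG peaks lay far more often at promoters than redrawn positions did. Of the 9165 centres, 2357 (25.7%) were within 1 kb of a protein-coding TSS, against 2.36% of redrawn positions (95% range 2.06 to 2.66), a ratio of 10.9. Introns held 2829 peaks (30.9% against 35.6% redrawn) and intergenic sequence 3776 (41.2% against 59.9%). Each of these permutation p-values was 0.002 (adjusted 0.00285), the smallest that 1000 redrawn sets can give. Coding exons held 91 peaks (0.993%, adjusted permutation p = 0.206), 3′ untranslated regions 104 (1.13%, adjusted p = 0.246) and 5′ untranslated regions 8 (adjusted p = 0.206). Another 1209 peaks (13.2%) lay 1 to 10 kb away, 3359 (36.7%) 10 to 100 kb away, and 2240 (24.4%) farther than 100 kb. The 916 highest-scoring peaks were at promoters in 8.41% of cases, 3.65 times the redrawn share.

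Forkhead sites marked the centres of Foxf2-FLAG peaks. RTAAAYA was present in the central 200 bp of 3742 peaks (40.8%, 39.8 to 41.8) and in 18.2% of upstream windows (17.4 to 19.03), a ratio of 2.24 (exact McNemar p = 4.73e-250). The stricter site GTAAACA was present in 15.3% against 3.30%, a ratio of 4.64. The forkhead site read backwards, a control of base composition, was slightly rarer at centres than in flanks (18.8% against 20.3%, exact McNemar test, adjusted p = 0.0175), but more frequent than in genome windows of equal GC content (1.16-fold, adjusted p = 2.27e-06). Of sites of other factors, RUNX (TGTGGTTW, 1.56-fold), SOX (AACAAWG, 1.19-fold) and CTCF (44 peaks against 13) were also more frequent, with adjusted p of 3.46e-06, 3.32e-04 and 1.15e-04. Where AAG or ATG follows RTAAACA, the same bases also match the SOX pattern, and such overlaps with forkhead sites were not removed. AP-1 (0.675-fold), GATA (0.569-fold) and the nuclear receptor half-site AGGTCA (0.696-fold) were less frequent, with adjusted p of 1.48e-05, 1.11e-13 and 2.49e-14. Against windows of equal GC content the AP-1 ratio was 0.834 and missed the threshold (exact McNemar test, adjusted p = 0.0718). The GC-rich sites of AP-2 (3.56-fold) and SP/KLF (6.08-fold) exceeded their flanks, but against genome windows of equal GC content the ratios were 1.13 and 1.20, while that of RTAAAYA was 2.80.

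**Figure D2:**
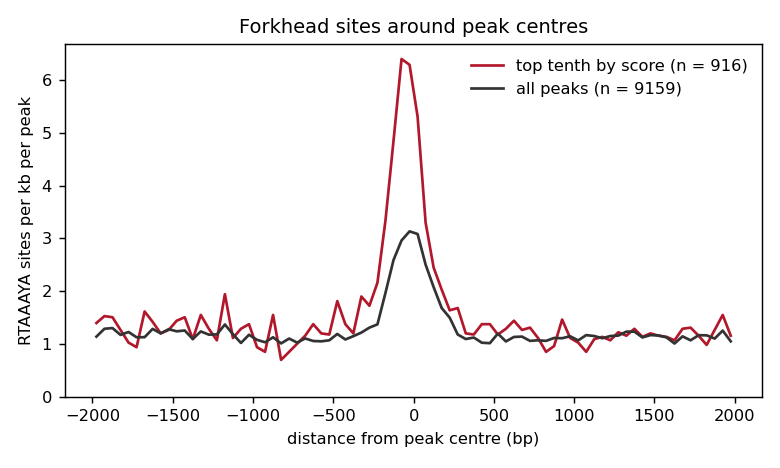
RTAAAYA sites per kb per peak (y axis) by distance from the peak centre in bp (x axis), in 50 bp bins, for all peaks (black, n = 9159) and the 916 highest-scoring peaks (red). Both lines rise from about 1 site per kb to a maximum within 100 bp of the centre, of 3.13 and 6.40 sites per kb.

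Peaks with a forkhead site scored higher than peaks without one. Their median score was 30 against 23, a difference of 7 (permutation p = 1e-05, the smallest that 100000 resamples can give). The share with RTAAAYA was 30.6% (28.6 to 32.7) among 2013 peaks with scores of 17 and 18, 33.8% at 19 to 22, 35.3% at 23 to 29, and 40.8% at 30 to 41. It was 64.8% (62.5 to 66.9) among the 1814 peaks with scores of 42 to 271, and the flanks stayed between 17.7% and 19.1%. With the deposited fold in place of the score, the difference in medians was -0.08 (permutation p = 0.0241), so the direction turned.

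**Figure D3:**
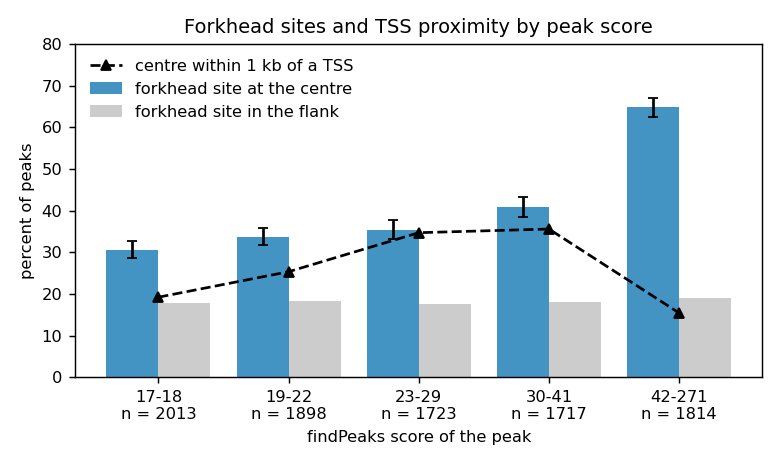
Percent of peaks (y axis) with RTAAAYA at the centre (blue, with Wilson 95% intervals) and in the flank (grey), by score bin (x axis, n under each). The dashed line is the percent of centres within 1 kb of a TSS, which was 35.6% at scores of 30 to 41 and 15.4% in the highest bin.

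Forkhead sites were less frequent in promoter peaks than in peaks farther away. RTAAAYA was present in 233 of 2357 peaks within 1 kb of a TSS (9.89%) and in 3509 of 6808 others (51.5%), an odds ratio of 0.103 (Fisher exact p = 1.79e-315). Within bins of equal GC content the odds ratio was 0.602 (Mantel-Haenszel, 95% interval 0.497 to 0.730). The promoter peaks held the site less often than their own flanks (17.9%, exact McNemar p = 2.69e-15), whereas GTAAACA was somewhat more frequent at their centres (4.71% against 3.44%, adjusted p = 0.0459). Promoter centres had a mean GC content of 68.3% against 43.7% for the other peaks. The backward site was present in 3.52% of promoter centres and 18.3% of their flanks, AP-2 in 31.7% and 4.12%, and SP/KLF in 12.5% and 0.891%.

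Among the 6808 distal peaks, the backward site was 1.15-fold as frequent as in flanks (exact McNemar test, adjusted p = 2.51e-05). ATAAACA (25.5% against 5.63% of flanks, 4.54-fold) and GTAAACA (18.9% against 3.25%, 5.83-fold) were the most enriched forkhead sequences. GTAAATA (2.19-fold), ACAAACA (1.61-fold) and ATAAATA (1.39-fold) followed, and GACGCAA, a site bound by some forkhead proteins, was not distinguishable from its flanks (22 peaks against 16, exact McNemar test, adjusted p = 0.418). RUNX sites were 1.97-fold, SOX sites 1.44-fold, the E-box CATCTG 1.32-fold and TEAD sites 1.28-fold as frequent as in flanks, with adjusted p of 3.35e-11, 9.86e-13, 9.86e-13 and 5.87e-08. Overlaps of the SOX pattern with forkhead sites were not removed here either. CTCF (3.45-fold), SP/KLF (1.82-fold) and AP-2 sites (1.62-fold) were also more frequent than in distal flanks, with adjusted p of 2.84e-04, 0.00463 and 5.48e-08. The split of other motifs and forkhead sequences by distance was chosen after the shares near and far from a TSS were seen. Homeobox sites (TAATTA) were at 1.03-fold (exact McNemar test, adjusted p = 0.802).

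Regulators of palate development were near Foxf2-FLAG peaks more often than genes with equally long surroundings. Of 39 such genes, 34 (87.2%) had an assigned peak, against 14.5 expected (ratio 2.34, adjusted permutation p = 0.0008, from the smallest p of 0.0002 that 10000 lists can give). After Twist1, the highest-scoring were Meox2 (157, intron), Lhx8 (99, promoter, 7 peaks in all) and Zeb2 (95, 30.2 kb from its TSS), which encode homeodomain and zinc finger transcription factors. The genes with none were Dlx1, Efnb2, Golgb1, Hoxa2 and Osr1. The best Meox2 peak (chromosome 12:37843390-37844143) had 167 ChIP tags against 8 input tags, a 14.95-fold excess (7.42 to 35.21).

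Genes of the hedgehog, Wnt and FGF signalling pathways, which act in the developing palate, were also overrepresented. Of 20 hedgehog genes, 16 had a peak (5.97 expected, ratio 2.68, adjusted permutation p = 0.0008). Among them were the palmitoyltransferase gene Hhat (score 156), the receptor gene Ptch1 (107) and the transcription factor genes Gli2 (79) and Gli3 (73), and Shh, Dhh and Ccnd1 were among the genes without a peak. Of 37 Wnt genes, 29 had a peak (14.2 expected, ratio 2.04, adjusted permutation p = 0.0008), led by Ror1 (90), Sfrp2 (80), Lrp5 (77) and Fzd1 (68). Of 22 FGF genes, 16 had one (8.05 expected, ratio 1.99, adjusted permutation p = 0.00192), led by Spry4 (84), Etv1 (55), Fgfr2 (53) and Fgf7 (51). Of 32 TGF-beta/BMP genes, 17 had one (11.8 expected, ratio 1.44), with Tgfbr3 at 138, Bmp7 at 80, Smad7 at 50 and Smad4 at 45, and the list did not pass the test (adjusted permutation p = 0.130).

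Extracellular matrix genes had peaks in 31 of 44 cases (14.96 expected, ratio 2.07, adjusted permutation p = 0.0008), with Col1a2 (score 100), Adamts5 (82), Itgb5 (77) and Col2a1 (71) highest. Forkhead genes themselves had peaks in 22 of 43 cases (12.4 expected, ratio 1.78, adjusted permutation p = 0.00427), led by Foxo3 (128), Foxp2 (90), Foxi2 (86) and Foxd1 (74). Of 20 osteogenic genes, 9 had a peak (4.98 expected, ratio 1.81, adjusted permutation p = 0.130), with Msx2 at 57, Phex at 53 and Sp7 at 39.

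Markers of other cell types did not exceed their matched lists. Peaks were assigned to 5 of 25 epithelial genes (among them Trp63, Dsg3, Krt8 and Grhl2, ratio 1.01, adjusted permutation p = 1.0) and 5 of 21 endothelial genes (Erg, Esam, Emcn, Cdh5 and Egfl7, ratio 0.839, adjusted p = 0.916). They were assigned to 4 of 20 neural genes (among them Gap43, Snap25 and Mtap2, ratio 0.582, adjusted permutation p = 0.300) and 1 of 18 muscle genes (Myog, ratio 0.241, adjusted p = 0.159). Of 20 blood and macrophage genes, 2 had a peak, Sfpi1 among them (ratio 0.700, adjusted permutation p = 0.916), and of 20 liver genes Apob and Apoh did (ratio 0.50, adjusted p = 0.470). Ribosomal protein genes had peaks in 12 of 52 cases (ratio 1.71, adjusted permutation p = 0.130), with Rps14 at 70, Rps12 at 61, Rpl5 at 57 and Rps27a at 38. Cell cycle genes had them in 8 of 28 (ratio 1.64, adjusted permutation p = 0.265), with Ccne2 at 60, Cdkn1c at 46, Cdk6 at 34 and Cdkn1a at 20.

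With only the 916 highest-scoring peaks, palate regulators alone passed the test (ratio 4.21, adjusted permutation p = 0.0032), the FGF ratio fell below 1 (0.854, adjusted p = 1.0) and forkhead (3.78, adjusted p = 0.0501), hedgehog (5.04, 0.052), matrix (3.29, 0.0501) and Wnt genes (1.90, 0.722) missed it, with fewer genes assigned. FGF genes also missed it with the 4582 highest-scoring peaks (ratio 2.05, adjusted permutation p = 0.054) and with assignment within 10 kb (2.09, adjusted p = 0.0718). With only peaks that held RTAAAYA, FGF (1.77, adjusted permutation p = 0.432) and Wnt genes (1.26, adjusted p = 0.803) missed it and ribosomal protein genes passed (3.19, adjusted p = 0.0269), and with promoter GC matched as well, forkhead genes missed it (1.39, adjusted p = 0.141).

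**Figure D4:**
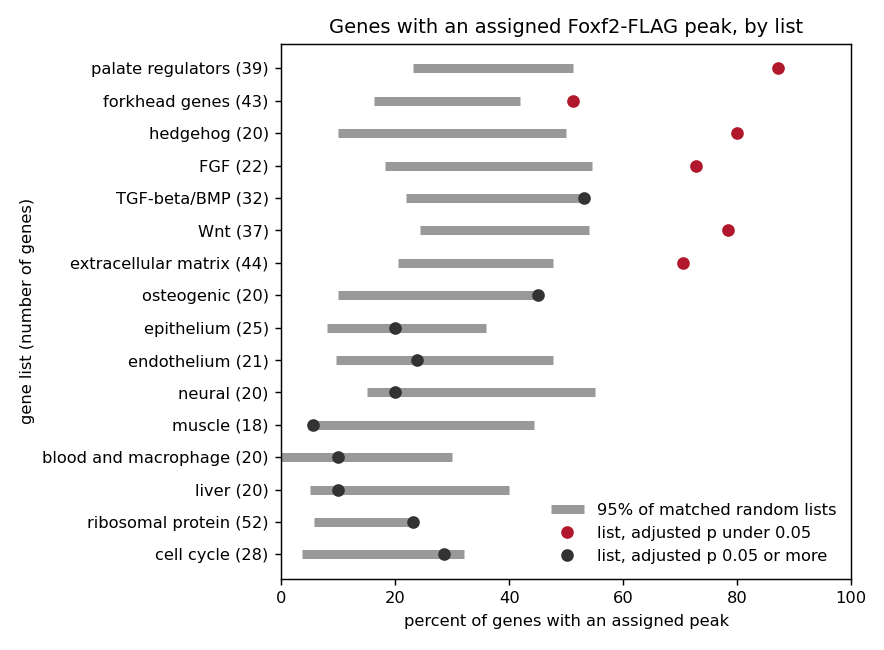
Percent of the genes of each list with an assigned Foxf2-FLAG peak (x axis), by list with its number of genes (y axis). Points are the lists, red where the adjusted p was under 0.05, and grey bars span 95% of 10000 matched random lists; palate regulators, at 87.2%, lie farthest right.

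Several genes studied in Foxf2 biology had assigned peaks, and Shh, Foxe1 and Bmp4 had none. The Foxf2 gene (chromosome 13:31717685-31723272) had 3 assigned peaks. One, 7.3 kb upstream at 31710133-31710633, had the highest score (49), with 48 ChIP tags against 3 input tags (11.5-fold, 3.69 to 57.5). Another, downstream of the gene at 31723917-31724940, had more tags, 255 against 12 (15.2-fold, 8.56 to 29.9), and held GTAAACA at 31724409-31724415 in the context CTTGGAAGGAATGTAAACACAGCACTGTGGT. Its paralogue Foxf1 (Foxf1a in the annotation) also had 3, the best at its promoter (chromosome 8:123606790-123607878, score 50, 81 tags against 5), with GTAAACA in the context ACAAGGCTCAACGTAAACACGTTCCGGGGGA.

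Ptch1, the hedgehog receptor gene, had 5 assigned peaks, 4 of them within the gene. The best lay in intergenic sequence 68.8 kb upstream, at chromosome 13:63742860-63743741, with 197 ChIP tags against 11 input tags (12.8-fold, 7.02 to 26.1) and 3 forkhead sites. One of these was GTAAACA at 63743323-63743329, in the context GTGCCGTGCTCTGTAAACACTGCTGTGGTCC. Osr2, a zinc finger factor gene needed for palatal growth, had 3 peaks, the best 12.2 kb upstream at chromosome 15:35213332-35213959 (score 66, 100 tags against 7). Pax9 had 3, the best 32.9 kb from its TSS in an intron of Slc25a21 (chromosome 12:57829146-57829905, score 72, 77 tags against 5). Msx1 had 3, the best at a score of 34, and Tgfb2 had 1 intronic peak (score 22, 21 tags against 1).

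Fgf18 had 3 peaks, the best 41.6 kb downstream of its TSS (chromosome 11:33004770-33005527, score 36, 65 tags against 3) and a weaker one at its promoter (score 25, 30 tags against 2). The peaks nearest to the TSSs of Shh, Foxe1 and Bmp4 were 98.8 kb, 27.8 kb and 196 kb away, with scores of 19, 22 and 18, and those at Shh and Foxe1 lay closer to the TSS of another gene.

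Peaks assigned within 100 kb gathered at some genes. Of 22359 protein-coding genes, 4925 (22.0%) had at least 1 assigned peak, and 6925 peaks (75.6%) were assigned. At least 3 peaks were assigned to 411 genes, against 197 in redrawn sets (ratio 2.09), and at least 5 to 84 genes, against 11.5 (ratio 7.29), each with permutation p = 0.002, the smallest possible. The transcriptional corepressor gene Bcor had 12, the 1 gene with at least 10 (0.036 expected, permutation p = 0.0739). Tgfbr3 and the transcription factor gene Tcf4 had 9 each. Arhgap24, Frzb, Bnc2, 4930558K02Rik and Igf1r had 8 each, and the teneurin genes Odz3 and Odz4 had 7 each. By length of its surroundings, at the same rate for all chromosomes, Bcor was expected to have 1.21 peaks and the Wnt antagonist gene Frzb 0.575. The Bcor peaks scored at most 49, and 4 of them held a forkhead site at the centre. Another peak lay within 10 kb of 14.9% of peaks, against 7.16% of redrawn positions (ratio 2.08, permutation p = 0.002). Without a limit on the distance of assignment, 806 genes had at least 3 peaks against 824 redrawn (ratio 0.979, permutation p = 0.302). At least 5 were then assigned to 249 genes against 265 (ratio 0.939), and at least 10 to 26 against 30.4 (ratio 0.857; permutation p = 0.132 and 0.374). Farther than 100 kb from a TSS lay 24.4% of peaks and 37.3% of redrawn positions, so fewer redrawn positions were assigned under the limit.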

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

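Of 48 alternatives to the main results, 43 were counted as the same. Tests had to keep direction and side of the threshold, and numbers of peaks and of lists called had to stay similar. Of 192 alternatives to single gene lists, 172 kept the side of the threshold, although ratios of lists not called could cross 1. Whole peak intervals, peaks with a forkhead site, peaks over 1 kb from a TSS and lists matched on promoter GC were chosen after seeing the data. Under every alternative run, promoters held more peaks than redrawn positions (8.41% to 29.8%), RTAAAYA or its variants exceeded the background (ratios 1.45 to 4.64), and promoter peaks held the site less often (odds ratios 0.0799 to 0.212, not adjusted for GC content; 0.602 within GC bins). Keeping only higher scores left 4582 and 916 peaks, by construction. Merging overlapping peaks, or peaks within 500 bp, left all 9165. With a minimum distance of 1000 bp between called peaks, neither could have come out otherwise, although both count among the 43. The difference in median score between peaks with and without a site became -0.08 with fold in place of the score (permutation p = 0.0241; otherwise 6 to 8, or 5.16 with -log10 of the p-value), and the cause was not tested. Genes with at least 3 peaks numbered 411, and 124, 4 and 229 with 4582 peaks, 916 peaks and a 50 kb limit. Each was above the redrawn number, but with no limit there were 806, below it. The 100 kb limit left out more of the redrawn positions (37.3%) than of the peaks (24.4%), but whether this was the cause was not tested. The 6 lists called became 1 with the 916 highest-scoring peaks, where fewer genes could be assigned, and 5 to 8 otherwise, not always the same lists; the FGF ratio became 0.854 there (adjusted permutation p = 1.0). Among list alternatives 10 missed the threshold, this one included, and 10 passed it anew, 4 of these for TGF-beta/BMP genes and 4 for ribosomal protein genes. The alternative without repeat-masked windows was not run, since the reference sequence carries no masking. No paired analysis was possible because each group had 1 library. Depth limits single peaks: with 1 input tag, the Tgfb2 fold of 15.04 had an interval of 2.42 to 622.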

Other observations

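The tests of input sampling noise and of X copy number, the split of motifs by distance, the promoter peaks of gene lists and the list matching on promoter GC were chosen only after the related result was seen. Counting promoter peaks alone, within 1 kb of a TSS, and matching random lists on promoter GC, 20 of 39 palate regulators had one (5.53 expected, ratio 3.62, adjusted permutation p = 0.0032) and 9 of 22 FGF genes did (3.07 expected, ratio 2.93, adjusted p = 0.0096). The other lists called in the report did not pass there: hedgehog (7 of 20, ratio 2.56, adjusted permutation p = 0.111), matrix (9 of 44, ratio 1.58, adjusted p = 0.512), Wnt (8 of 37, ratio 1.22, adjusted p = 0.963) and forkhead genes (9 of 43, ratio 1.09, adjusted p = 1.0). Of 8192 sequences of 7 bases tested in the 6808 distal peaks, 839 were more frequent at centres than in flanks and 764 less frequent. A 6-base part of the forkhead site was held by 33 of the 839, by 12 of the 20 with the smallest p and by the 10 with the smallest p. CATCTGG, which holds the E-box CATCTG, was in 421 centres against 242 flanks (ratio 1.74, exact McNemar test, adjusted p = 3.03e-10).

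A window of 1 Mb around Twist1 held 8 peaks. Besides the peak in Hdac9, the peak with the most ChIP tags was intergenic, at chromosome 12:34359620-34360912, with 441 ChIP tags against 18 input tags (17.6-fold) and 3 forkhead sites. It was nearest to Twistnb, 245.8 kb from its TSS, and was left unassigned. A peak with 66 tags lay 0.8 kb from the Twist1 TSS and held no forkhead site. Matched on promoter GC as well as territory, 5 of the 6 lists called stayed past the threshold, all but the forkhead genes. Promoter GC, measured at 1 TSS per gene and matched in broad bins, thus did not account for these 5 lists by itself. Expression and open chromatin were not matched.

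Promoter peaks seldom held a forkhead site (crude odds ratio 0.103). Within bins of equal GC content the Mantel-Haenszel odds ratio was 0.602 (0.497 to 0.730), so most of the difference went with GC content. The backward site was also rarer in promoter centres (3.52%) than in distal ones (24.0%). Its odds ratio within GC bins was not computed. Whether the remaining difference is particular to the forkhead site therefore stays open. At equal ChIP tags, the input of promoter peaks differed from that of the others by -0.116 tags (permutation p = 0.0005, the smallest possible), a small deficit at promoters, so lower input coverage may have let some promoters through and stays open. Ribosomal protein genes, promoters open in every cell, had a promoter peak no more often than genes of equal GC (ratio 0.924, permutation p = 1.0), which does not decide whether some promoters are collected without the factor, since a library from untagged embryos was not used here. No biological explanation, such as recruitment through other proteins, was tested.

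Most peaks, low-scoring ones above all, passed the 10-fold requirement with input below its genome mean. The median peak had 4.17 times the genome mean of ChIP tags but a fold of 12.9 over input. The median input was 0.219 times its own genome mean, and 95.2% of peaks lay below that mean. Input lay below it in 99.95% of peaks with scores of 17 and 18. It also did so in 66.9% of the 916 highest-scoring peaks, whose median input was 0.832 times the mean. If low-scoring peaks were chance positions in the genome, sites should be no more frequent at their centres than beside them. Of 1494 distal peaks with scores of 17 and 18 and at most 1 input tag, 36.2% held a site against 18.3% of flanks (ratio 1.97, 1.75 to 2.24). That argues against all of them being chance positions. Peaks also had to pass a threshold on ChIP tags, which can by itself enrich sites. The ratio therefore cannot decide whether chance lows of the input let them pass the 10-fold requirement. How many of them passed on such a low stays open. The folds of peaks with little input, high-scoring ones included, may be too high.

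The X chromosome had 0.321 times the autosomal peak density (0.277 to 0.370), and 0.229 times (0.125 to 0.387) among the 916 highest-scoring peaks. Fewer genes on the X did not account for it alone, since promoter peaks per gene were also fewer (0.509, 0.378 to 0.671). With autosomal scores thinned to 75%, as in a pool with as many males as females, 0.609 of the peaks would remain, and with thinning to 50%, as in males only, 0.321. On that basis, copy number alone reached the observed ratio only near thinning to 50%. The thinning to 75% counted both X chromosomes of a female as bound alike, which was not tested. If 1 of them is not bound, thinning to 50% applies to females as well, so the ratio does not give the sexes of the embryos. Fewer genes and copy number together were not tested, and the interval of promoter peaks per gene (0.378 to 0.671) holds 0.609. The thinning treated scores as tag counts, although a Foxf2 peak with 255 tags had a score of 30. Since the labels used here give no sex, copy number cannot be told apart from a biological difference.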
